A study of Mus musculus with 11 samples.

How the data were processed

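Total RNA of mouse islets was extracted with TRIzol, made into libraries with a NuGEN Ovation RNA-Seq kit and sequenced as 75-base single-end reads, per the labels' protocols. Male mice of 3 months were used. Tamoxifen was given at 10 mg per day on 2 consecutive days at 45 to 60 days of age, 2 weeks before PPx, and islets were taken 6 days after PPx, per the labels' protocols. The submitters' processing notes name HISAT2, SAMtools, featureCounts and edgeR and the builds GRCm38 and mm10; which of these tools made the table, with which gene annotation and filters, is not given.

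The authors deposited 1 table with 1 column per library, of values they call normalized read counts. These were taken as FPKM, the reads of a gene per kilobase of its length, scaled to the reads of the library, as the authors deposited them. The unit was inferred from the values: 0.00065% of values above 0 were whole numbers, the columns summed to between 252888 and 446118 and not to a shared total, and the smallest values of short genes followed steps that scaled with the inverse of gene length. Whole read counts cannot be recovered from such values, so total reads and counting intervals are not given and the depth of a library was estimated only relative to the deepest one, from the 5th percentile of its values above 0 multiplied by transcript length. No scaling between libraries beyond the total is stated, and a library in which 1 RNA takes a large share has lower values for all other genes.

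The table had 20068 entries. For 26 of them a date stood in place of the gene symbol; they held 0.092% of the sum and were left out, which left 20042 genes. Transcripts of the mitochondrial genome were not among them, and 30.6% of values were 0. Some genes that all cells use were listed at 0 in single libraries or, as in KO after PPx, in a whole group. Whether these are true zeros or failed estimates is not known, so a value of 0 is given as listed. A log2 difference fitted against a group listed entirely at 0 is given only for flagged interaction terms and is no measure of size. The kit does not record strand as far as the labels say, so a gene and an overlapping or antisense gene cannot be separated. Near-identical genes (Ins1 and Ins2, Hspa1a and Hspa1b, the amylase and Reg genes) are uncertain because it is not stated how shared reads were counted. Coordinates are from GENCODE M21 on GRCm38, matched by symbol.

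Libraries were grouped by genotype and PPx as labelled, each taken as a separate sample. Values were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 libraries were tested, 13295 of 20042. Differences were tested with limma 3.58.1 in R 4.3.3 with an intensity trend in the variance, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A model with the 4 groups gave KO against control without PPx and after PPx, PPx against no PPx in control and in KO, and the interaction. An additive model gave the effect of genotype with PPx as a term and of PPx with genotype as a term. Gene lists were tested with camera from limma at a preset correlation of 0.01, which compares a list with all other tested genes; of 29 gene lists, 26 had at least 3 tested genes. Lists recalled from the published study are named as such. List means were also compared by exact permutation of the libraries.

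The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. In each comparison the rule names Arid1a; the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap between the groups and whose higher group has a mean of at least 5, predicted genes excepted; up to 4 members with the smallest p of each list that passed or holds a called gene; Ins1, Ins2, Gcg, Sst, Ppy and Mki67; and, where no gene passed, the 5 smallest p in each direction. From the lists, a selection of those members is named. Alternatives were other pseudocounts, filters and scalings (TMM and median-of-ratios factors computed from the FPKM), limma without the trend or with array weights, a fit of the 2 groups compared alone, the mean of the acinar markers as a covariate, leaving out each library in turn, and for lists an estimated correlation and fry. Settings added after the data were seen left out both KO libraries after PPx, left out control library 9 and KO library 12 without PPx, removed a trend on transcript length (known for 96% of tested genes), or kept protein-coding genes only.

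Data were simulated with normal noise, independent between genes and of the same spread for a gene in all libraries. Changes were planted only in genes above a low mean value, and no library was made to stand apart. The rates below therefore describe a simpler case than the real data. The test was run on such simulated data with 200 changed genes among 13295 and the real group sizes. For a log2 change of 1 and of 2 it recovered 28% and 81% of the genes for KO against control without PPx, 15% and 65% after PPx, 20% and 69% for PPx in control, 48% and 79% for PPx in KO, 6% and 36% for the interaction, 65% and 95% for genotype with PPx as a term, and 70% and 93% for PPx with genotype as a term, with 2 to 10 false calls.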

Results

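Islets of Langerhans, the hormone-secreting cell clusters of the pancreas, were isolated from male mice aged 3 months, and their total RNA was sequenced. All mice were homozygous for a floxed allele of Arid1a, which encodes a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex. Controls carried the floxed allele only, and knockout (KO) mice also carried UBC-CreERT2, a tamoxifen-inducible Cre recombinase driven by the ubiquitin C promoter. Some of the mice underwent partial pancreatectomy (PPx), a surgical removal of part of the pancreas after which the remaining islets can expand, and their islets were taken 6 days later. The series held 2 control and 5 KO libraries without PPx, and 2 control and 2 KO libraries after PPx, 11 in all. The design addresses what loss of Arid1a changes in islets at rest, what PPx changes, and whether the response to PPx depends on Arid1a. Since controls lacked UBC-CreERT2, an effect of the recombinase cannot be told apart from loss of Arid1a. The values are read as FPKM (fragments per kilobase, scaled to the reads of the library). Error terms are SD over the libraries of a group unless SE is named.

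The 2 KO libraries after PPx stood apart from the other 9. Rn45s, the 45S precursor of ribosomal RNA, made up 30.8% of the summed FPKM in KO after-PPx library 7 and 22.9% in library 8, against 4.7% to 14.1% in the other libraries. They had 11213 and 12948 genes above 0, where the others had 13576 to 14857, and their summed FPKM of 252888 and 278183 lay below the 344547 to 446118 of the rest. Total reads are not given, so depth was estimated from the smallest values in each library. By that measure KO after-PPx libraries 7 and 8 had 0.281 and 0.314 of the depth of the deepest library, and the others 0.45 to 1. They listed 199 and 54 genes at 0 that had a median above 10 FPKM over the libraries, against 1 to 19 genes elsewhere. Their median correlation with the other libraries was 0.777 and 0.801, against 0.888 to 0.921, and the first principal component, with 49.9% of the variance, separated them at -122 and -60.2 from a range of -16.7 to 45.4.

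**Figure D1:**
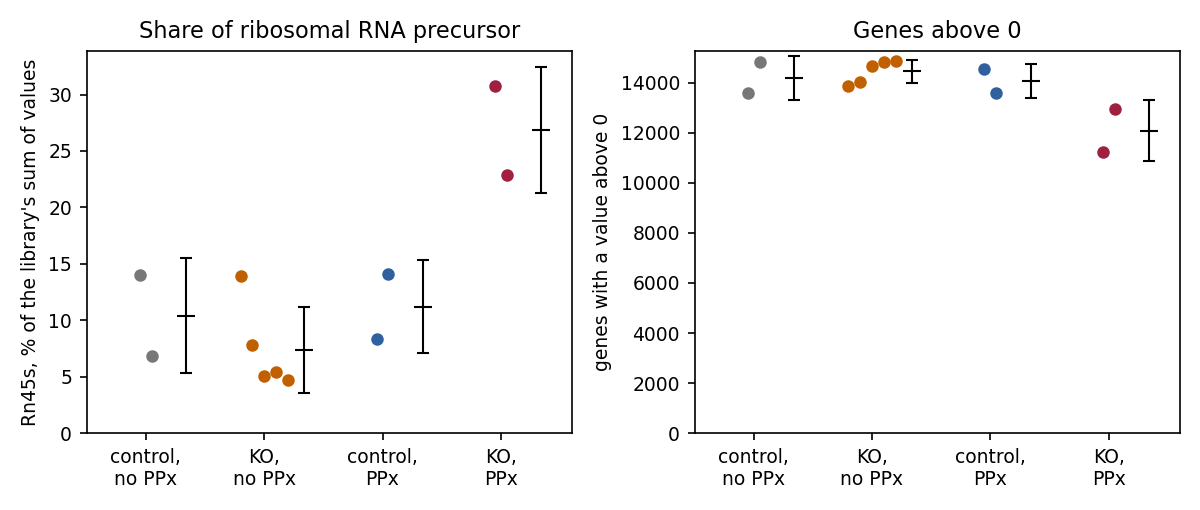
Each point is 1 library, grouped by genotype and surgery, with the group mean and SD. The panels give the percent of summed FPKM taken by Rn45s and the number of genes above 0. The 2 KO libraries after PPx, at 30.8% and 22.9% Rn45s, lie above the other 9, which lie at 4.7% to 14.1%.

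Arid1a RNA (chromosome 4, 133679008 to 133756769, minus strand, GRCm38) was 30.9 ± 1.52 FPKM in controls without PPx (n = 2) and 24.9 ± 4.59 in KO without PPx (n = 5). After PPx it was 39.1 ± 4.44 in controls and 29.6 ± 4.44 in KO (n = 2 each). Without PPx the control libraries had 32.0 and 29.8 FPKM, and KO libraries 12, 13, 15 and 16 had 20.7, 24.7, 22.2 and 24.2. The library labelled KO no-PPx 14 had 32.6, above both controls of its state. After PPx the controls had 42.3 and 36.0 and the KO libraries 32.8 and 26.5. None of the differences passed the test. The log2 difference of KO from control was -0.32 (SE 0.19, adjusted p = 1 by limma) without PPx, -0.39 (SE 0.23, adjusted p = 0.263) after PPx, and -0.35 (SE 0.15, adjusted p = 0.836) with PPx as a term. The difference after PPx was absent with TMM scaling (0.03, adjusted p = 0.966) and with median-of-ratios scaling (0.11, adjusted p = 0.83). In KO islets Arid1a was not called for PPx as deposited (0.25, adjusted p = 0.303) but was called higher after PPx with TMM scaling (0.83, adjusted p = 0.0176). That scaling raises all genes of the KO libraries after PPx. A value over the whole gene also counts transcripts that lack a deleted exon, so it does not measure excision.

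**Figure D2:**
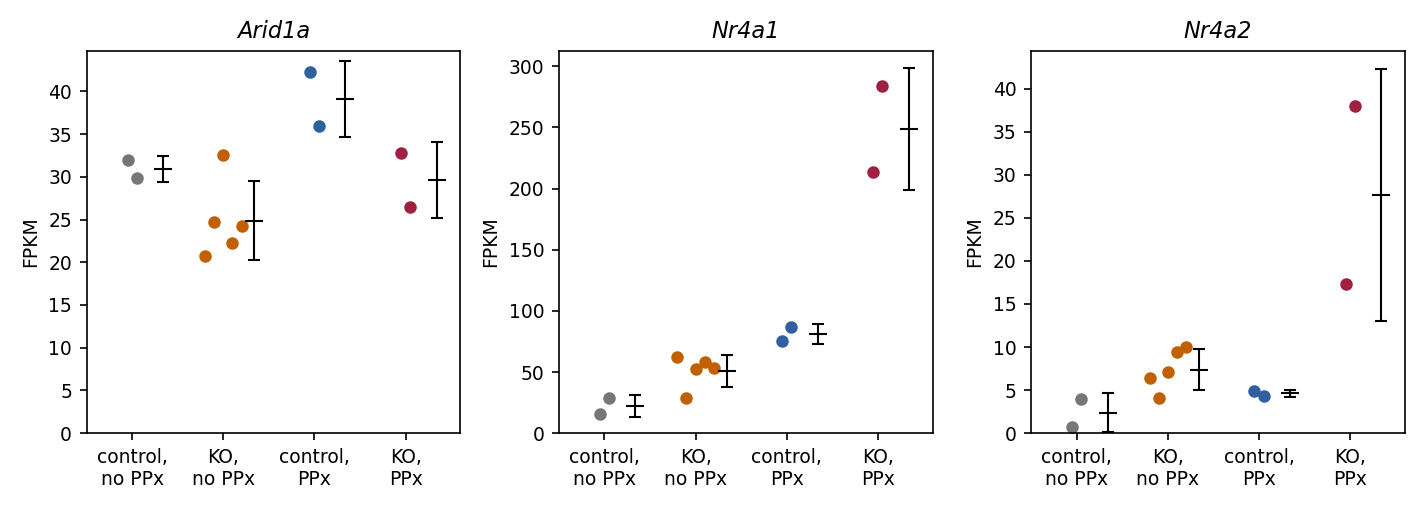
FPKM of Arid1a, Nr4a1 and Nr4a2 in each library (points), with the mean and SD of each group. The library labelled KO no-PPx 14 (Arid1a 32.6) lies above both controls without PPx, and Nr4a1 ranges from 15.9 in a control without PPx to 284 in a KO library after PPx.

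Without PPx, KO islets had higher mean levels than controls of the immediate early genes, which cells switch on within minutes of a stimulus and which also rise when tissue is dissociated. The list of 16 also holds the heat shock genes Hspa1a and Hspa1b, whose reads cannot be told apart. All 16 measured members had a positive log2 difference, with a median of 0.60, but none was called and the list did not pass with an estimated correlation (adjusted p = 0.636). The values depended on which control was kept: the difference was 0.46 without control library 9 and 1.36 without control library 11 for Dusp1, 0.19 and 1.29 for Btg2, -0.05 and 1.56 for Junb, and -0.04 and 1.13 for Zfp36. Nr4a1, an orphan nuclear receptor of this class, was at 22.3 ± 9.08 FPKM in controls (n = 2) and 50.7 ± 13.0 in KO (n = 5), and Fosb, a subunit of the AP-1 transcription factor, at 48.9 ± 13.3 and 92.9 ± 27.7. None of the hormone genes passed the test. The log2 difference was -0.04 (SE 0.57) for Ins1 and 0.19 (SE 1.11) for Ins2, which encode insulin, 0.00 (SE 0.56) for Gcg (glucagon), 0.56 (SE 0.33) for Sst (somatostatin) and -0.73 (SE 0.49) for Ppy (pancreatic polypeptide). Mki67, a marker of dividing cells, stood at 1.41 and 0.895 FPKM on average.

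Of 13295 genes tested, limma called 0 at an adjusted p below 0.05 in this comparison, and 299 had an unadjusted p below 0.05, where 665 are expected by chance. It also called 0 with array weights, without the intensity trend, and after TMM or median-of-ratios scaling, but 1 without control library 9 and 2 without control library 11. By camera, 2 of 26 gene lists passed with a preset correlation: the immediate early genes (adjusted p = 1.44e-08, adjusted p = 0.636 with an estimated correlation) and the 3 Nr4a receptors (adjusted p = 0.00979, adjusted p = 0.636 with an estimated correlation). None of the immediate early genes was called over all genes or adjusted over the list alone. Of the Nr4a receptors, 0 were called over all genes and 2 adjusted over the list alone, Nr4a1 (log2 difference 1.16, SE 0.31) and Nr4a2 (1.44, SE 0.44). Without control library 9 they were 0.75 and 0.69, and without control library 11 they were 1.57 and 2.2. This list was recalled from the published study and is not independent evidence. Dusp1, a phosphatase that switches off MAP kinases, had a difference of 0.91 (SE 0.29) and Klf4 0.85 (SE 0.28).

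The genes with the smallest p without PPx were Toporsos and Fam46a. Toporsos was listed at 0 in both controls and at 4.27, 7.95, 6.39, 3.72 and 5.55 FPKM in the 5 KO libraries (adjusted p = 0.347). Fam46a was 17.0 ± 0.489 in controls and 32.3 ± 0.863 in KO (log2 difference 0.89, SE 0.14, adjusted p = 0.347). Sema3c, a secreted semaphorin, had 0.271 ± 0.25 and 3.75 ± 1.28 FPKM, and Fam195a and 3010026O09Rik were next. On the lower side were Pnp2, Mir7006, Smim24, Ms4a7 and Polr2k, each listed at 0 in 3 or 4 of the 5 KO libraries and adjusted p = 1. The library labelled KO no-PPx 14, with Arid1a above both controls, is among the KO libraries here.

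After PPx, KO islets had higher Nr4a receptors than control islets and lower values of most genes called, Ins1, Gcg, Pcsk1 and Uqcrc2 among them. Nr4a1 (chromosome 15, 101254269 to 101274795, plus strand) rose from 81.1 ± 7.82 to 248 ± 49.9 FPKM and Nr4a2 (chromosome 2, 57106830 to 57124003, minus strand) from 4.62 ± 0.379 to 27.6 ± 14.6 (n = 2 each). Ins1 fell from 18878 ± 6420 to 3277 ± 677 FPKM and Gcg from 9034 ± 2606 to 1397 ± 5.73. Pcsk1, the convertase that cuts proinsulin, fell from 138 ± 18.3 to 28.0 ± 0.439, and Slc2a2, the beta cell glucose transporter, from 183 ± 26.0 to 39.3 ± 21.1. Limma called 1400 of 13295 genes, 42 higher and 1358 lower in KO, 97% of them lower. The KO libraries of this comparison are those with the high Rn45s share and low depth.

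All 3 Nr4a receptors rose (3 adjusted over the list alone; camera adjusted p = 1.54e-06, adjusted p = 0.189 with an estimated correlation), with log2 differences of 1.59 (SE 0.37, adjusted p = 0.0289), 2.25 (SE 0.53, adjusted p = 0.0301) and 1.47 (SE 0.38, adjusted p = 0.0371) for Nr4a1, Nr4a2 and Nr4a3. Of the 18 ERK pathway feedback and target genes, 1 rose, 0 fell and 17 did not pass (0 adjusted over the list alone; camera adjusted p = 0.000163, adjusted p = 0.551 with an estimated correlation): Errfi1, an inhibitor of the EGF receptor, rose by 1.45 (SE 0.40). The 16 immediate early genes had a median of 0.53 and 14 positive values, and the list passed (camera adjusted p = 3.03e-09, adjusted p = 0.37 with an estimated correlation), but 0 members rose over all genes or adjusted over the list alone. With TMM scaling 6 of them rose and with median-of-ratios scaling 7, but both scalings raise all genes of the KO libraries after PPx, so these counts add no support. The TGF-beta and BMP list also stood above the other genes, with a median of 0.40 over 13 genes, 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 5.79e-06, adjusted p = 0.551 with an estimated correlation).

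Of 27 beta cell identity and function genes 9 fell, 0 rose and 18 did not pass (14 fell adjusted over the list alone; median -0.96; camera adjusted p = 0.0347, adjusted p = 0.819 with an estimated correlation). Pcsk1 fell by 2.25 (SE 0.41, adjusted p = 0.0153) and Slc2a2 by 2.29 (SE 0.51, adjusted p = 0.0254). Trpm5, a cation channel, fell by 1.35 and Glp1r, the receptor of the incretin GLP-1, by 1.02. With TMM scaling Pcsk1 kept its call (adjusted p = 0.0189), but Slc2a2, Trpm5 and Glp1r did not (adjusted p = 0.0615, 0.0786 and 0.0924). Ins1 (log2 difference -2.50, SE 0.68, adjusted p = 0.0441) and Gcg (-2.66, SE 0.67, adjusted p = 0.0356) also lost their calls with TMM scaling (adjusted p = 0.0855 and 0.0607). Ins2, nearly identical to Ins1 in sequence, was at -2.38 (SE 1.33, adjusted p = 0.25), Sst at -1.23 (adjusted p = 0.0681), Ppy at -1.63 (adjusted p = 0.0917) and Mki67 at 0.24 (adjusted p = 0.724).

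Of 20 oxidative phosphorylation genes 7 fell (13 adjusted over the list alone; median -1.10; camera adjusted p = 0.00205, adjusted p = 0.819 with an estimated correlation). Uqcrc2, a core subunit of complex III, fell from 21.9 ± 7.19 to 4.37 ± 0.924 FPKM (log2 difference -2.07, SE 0.36, adjusted p = 0.0124). Of 20 unfolded protein response genes 3 fell (7 adjusted over the list alone; camera adjusted p = 0.0463, adjusted p = 0.822 with an estimated correlation), among them Sdf2l1, a cofactor of the chaperone BiP, from 27.6 ± 3.80 to 3.76 ± 1.39 FPKM, Hsp90b1 and Manf. With TMM scaling Sdf2l1 kept its call, and Hsp90b1 (-0.49, adjusted p = 0.129) and Manf (-0.95, adjusted p = 0.0887) lost theirs. Macrophage and dendritic cell markers were not called as a list, but 4 of 13 fell (4 fell and 1 rose adjusted over the list alone), all genes of class II antigen presentation. These were Cd74, from 71.4 ± 6.14 to 12.9 ± 8.14 FPKM (log2 difference -2.51, SE 0.35, adjusted p = 0.00538), H2-Aa, H2-Ab1 and H2-Eb1. With TMM scaling H2-Ab1 and H2-Eb1 lost their calls (adjusted p = 0.0565 and 0.0704). Tgfa, a ligand of the EGF receptor, fell from 8.10 ± 0.919 to 1.27 ± 1.03, as 1 of 6 ErbB ligands and receptors (1 adjusted over the list alone), a list recalled from the study and so not independent evidence. Usp18, which removes ISG15 from proteins, fell from 14.3 ± 3.43 to 0.884 ± 0.387. Acinar, stromal and Reg family genes stood above the other genes (camera adjusted p = 0.000335, 0.0025 and 0.0347; each adjusted p = 0.819 with an estimated correlation) with 0 members rising, and 1 stromal gene, the pericyte marker Rgs5, fell by 1.06. Rgs5 lost its call with TMM scaling (-0.66, adjusted p = 0.122) and was called in 2 of 11 fits that left out 1 library.

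Most of the falls that the rule names after PPx were short nuclear-encoded transcripts listed at 0 in both KO libraries. Whether these are true zeros or failed estimates of the tool that made the table is not known, and no size is given. Cox6c, a subunit of cytochrome c oxidase, had 45.0 and 20.4 FPKM in the controls, Usmg5 (an ATP synthase subunit) 53.8 and 14.3, Ndufc1 19.4 and 15.0, Polr2f 16.1 and 14.5, and Atp5e 15.8 and 13.7. Mir344c and Hba-a2 were also listed at 0 in both, and Rpl37a, a ribosomal protein gene, had 74.3 and 55.7 in controls against 13.3 and 0. Of the 1400 genes, 169 had a group listed entirely at 0, for which no fold is given. The rises it names were in short RNAs: Mir328, Mir6984, Mir7067, Snora15, Mir1224, Mir6927, Scarna10 and Mir6945. Mir6984 (chromosome 19, 3288920 to 3288983) had 0.0690 and 0 FPKM in controls and 16.0 and 16.6 in KO. Reads of such short genes without strand cannot be told from reads of a host transcript.

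The count after PPx depended on scaling and on single libraries. TMM scaling, which moved the median of all genes from -0.47 to -0.14, gave 118 higher and 656 lower genes, median-of-ratios scaling (median -0.08) 149 and 532. Of the 1400 genes, 387 were called under both and with a trend on transcript length removed as well. The count was 53 without control library 5, 227 without control library 6, 824 without KO library 7 and 4038 without KO library 8, and 750, 786, 640 and 667 without KO no-PPx libraries 13, 14, 15 and 16. Only 44 genes were called in every such fit. Fitted on the 4 libraries after PPx alone, limma called 0, with 2267 genes at an unadjusted p below 0.05. Of the 11 fits that left out 1 library, Nr4a1 was called in 9, Nr4a2 in 8, Nr4a3 in 5 and Errfi1 in 4. Sdf2l1 was called in 11, Cd74 and Usp18 in 10, and Ins1 and Gcg in 3.

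In control islets no single gene passed the test for PPx, and the differences seen were in list means, higher for immediate early genes and stromal markers and lower for acinar genes. Dnajb1, a co-chaperone of Hsp70, was at 13.3 ± 1.29 FPKM without PPx and 69.8 ± 23.1 after it (n = 2 each; log2 difference 2.28, SE 0.31, adjusted p = 0.263), and Hspa1a, an inducible Hsp70 gene whose reads cannot be told from its near-copy Hspa1b, at 17.4 ± 15.0 and 206 ± 91.8. Nr4a1 was at 22.3 ± 9.08 and 81.1 ± 7.82 (log2 difference 1.87, SE 0.37, adjusted p = 0.552). Dpp4, the protease that inactivates incretins, was lower (11.3 ± 2.06 against 2.85 ± 0.764, adjusted p = 0.387), as was Greb1l (4.91 ± 0.633 against 0.407 ± 0.108, adjusted p = 0.413). Limma called 0 of 13295 genes, and 573 had an unadjusted p below 0.05 against 665 expected by chance. It called 0 with array weights and under each scaling, 1 without control no-PPx library 9, 1 without KO no-PPx library 15 and 5 without control after-PPx library 5.

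Among 9 lists that passed by camera, the immediate early genes had 16 of 16 positive values (median 0.78, 0 called over all genes and 3 adjusted over the list alone, adjusted p = 1.83e-10, adjusted p = 0.313 with an estimated correlation) and the Nr4a receptors 3 of 3 (1 adjusted over the list alone, adjusted p = 0.000214, adjusted p = 0.313 with an estimated correlation). Leaving out 1 library moved Junb between -0.43 and 1.18 and Btg2 between -0.51 and 0.59, while Fosb stayed at 0.5 to 1.05 and Klf4 at 0.68 to 0.97. Stellate cell, fibroblast and pericyte markers were positive in 17 of 18 (median 1.17; adjusted p = 5.68e-07, adjusted p = 0.576 with an estimated correlation). Col1a1, which encodes a chain of type I collagen, was at 0 and 0.475 FPKM without PPx and 2.08 and 59.1 after it, so that after-PPx library 6 carried most of this difference. Endothelial markers (14 of 14 positive, adjusted p = 1.28e-05), interferon response genes (14 of 15, adjusted p = 6.09e-05), SWI/SNF subunits (21 of 24, adjusted p = 0.000461), targets of the Hippo pathway (9 of 9, 1 adjusted over the list alone, adjusted p = 0.000482) and macrophage and dendritic cell markers (10 of 13, adjusted p = 0.0185) also stood higher. With an estimated correlation their adjusted p = 0.576, and adjusted p = 0.838 for the macrophage list. Acinar markers, the digestive enzyme genes of exocrine pancreas, were lower in 26 of 27 (median -2.32; 0 called over all genes or adjusted over the list alone; adjusted p = 5.68e-07, adjusted p = 0.793 with an estimated correlation). Their mean log2 value was 2.59 and 7.80 in the controls without PPx and 2.77 and 3.27 after it, so control no-PPx library 11 alone carried the difference. Beyond Dnajb1 and Nr4a1, the smallest p on the higher side belonged to Arhgap36, Mir490 and Mir1956, and beyond Dpp4 and Greb1l on the lower side to Mir186, Lipt2 and Mir15a. No hormone gene passed the test (Ins1 0.12, SE 0.68; Ins2 -0.13, SE 1.33; Gcg 0.06, SE 0.67; Sst -0.15, SE 0.39; Ppy -0.45, SE 0.58), nor did Mki67 (0.25, SE 0.41).

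**Figure D3:**
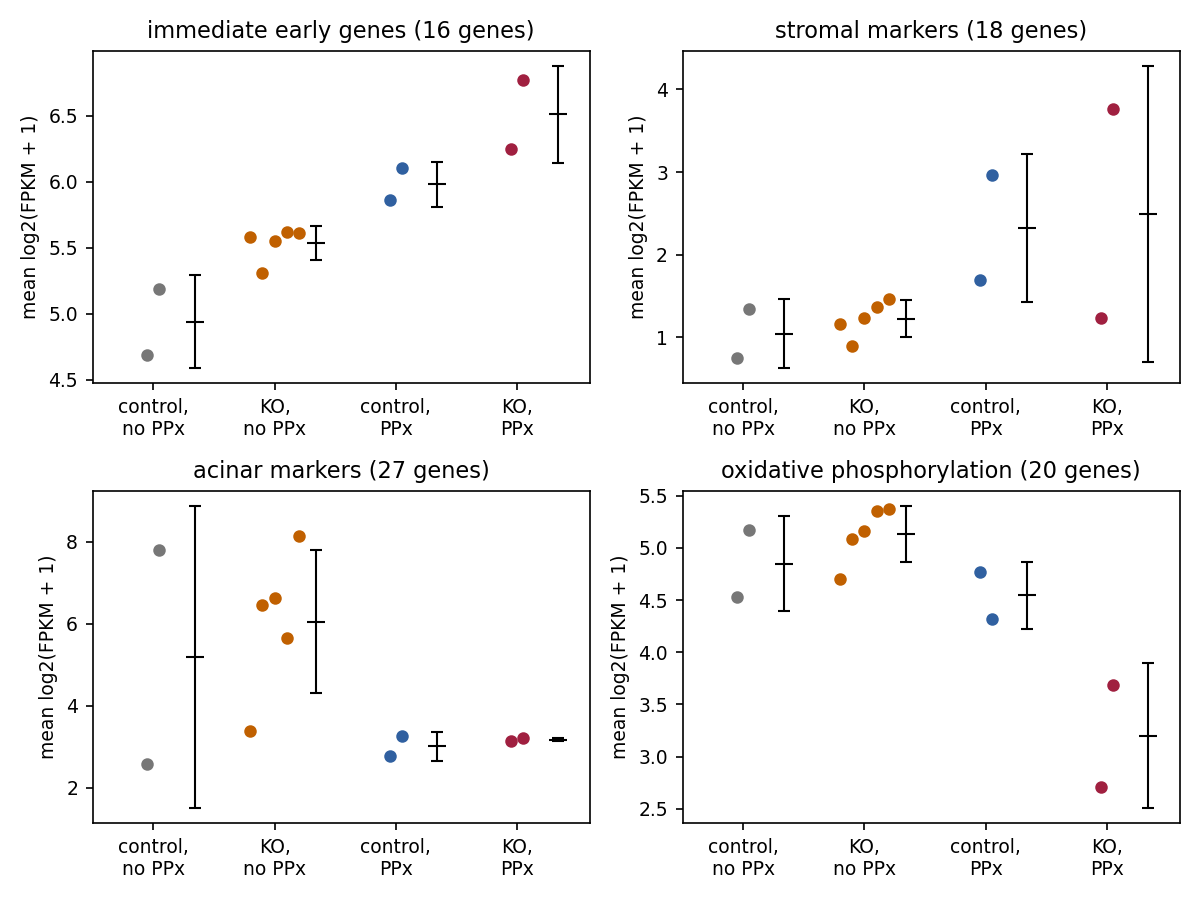
Mean log2(FPKM + 1) of 4 gene lists in each library (points), with the mean and SD of each group: 16 immediate early genes, 18 stromal markers, 27 acinar markers and 20 oxidative phosphorylation genes. The 16 immediate early genes include Hspa1a and Hspa1b. Immediate early means are 4.69 to 5.62 without PPx and 5.86 to 6.77 after it, and oxidative phosphorylation means are 2.71 and 3.69 in the KO libraries after PPx against 4.32 or more elsewhere.

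In KO islets after PPx, the genes called higher included the Nr4a receptors, Hspa1a, Hspa1b, Dnajb1 and Col1a1, and those called lower included Ins1, Gcg, Sst, Uqcrc2, Sdf2l1 and Fdps. Nr4a1 rose from 50.7 ± 13.0 FPKM (n = 5) to 248 ± 49.9 (n = 2), Dnajb1 from 18.5 ± 4.69 to 101 ± 10.6 and Hspa1a from 21.1 ± 14.6 to 185 ± 107. Ins1 fell from 17015 ± 4621 to 3277 ± 677 FPKM, Gcg from 9310 ± 3595 to 1397 ± 5.73, Sst from 3807 ± 840 to 981 ± 210 and Ppy from 1530 ± 551 to 588 ± 212. Limma called 5588 genes, 444 higher and 5144 lower, so 92.1% were lower. The after-PPx libraries here are again the 2 with the high Rn45s share, and the KO group without PPx includes the library labelled KO no-PPx 14, whose Arid1a value exceeded both controls.

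All 3 Nr4a receptors rose (3 adjusted over the list alone; camera adjusted p = 4.14e-06, adjusted p = 0.241 with an estimated correlation), Nr4a1 by 2.30 (SE 0.31, adjusted p = 0.000797) and Nr4a3 by 2.15 (SE 0.31, adjusted p = 0.00109). Of 16 immediate early genes 6 rose, 0 fell and 10 did not pass (6 adjusted over the list alone; median 0.81; camera adjusted p = 9.15e-11, adjusted p = 0.271 with an estimated correlation), among them Fosb (log2 difference 0.87), Jun (0.69), Klf4 (0.90) and Zfp36, which degrades inflammatory mRNAs (1.36). Also among the 6 were Hspa1a (3.20) and Hspa1b (3.32), whose reads cannot be told apart. With TMM scaling 15 of the 16 rose and with median-of-ratios scaling 16. These counts add no support, since both scalings raise all genes of the KO libraries after PPx (TMM factors 0.632 and 0.869). Of 11 fits that left out 1 library, Fosb and Klf4 were called in 8, Jun in 9 and Zfp36 in 11. The Klf4 difference ran from 0.39 to 1.42 in them. Of 18 ERK feedback and target genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.000248, adjusted p = 0.621 with an estimated correlation). The ERK list stood above the other genes, where the median of all tested genes was -0.63. Errfi1 rose by 1.37 and Phlda1 by 1.31, while Etv5 and Etv1, ETS transcription factors induced by ERK, fell by 1.20 and 1.46.

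Of 18 stromal markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; median 1.02; camera adjusted p = 1.13e-08, adjusted p = 0.621 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) was at most 2.55 FPKM without PPx and at 8.52 and 109 after it (log2 difference 4.38, SE 1.10, adjusted p = 0.0105). Fn1 (fibronectin), listed at 0 in 4 of the 5 KO libraries without PPx, was at 1.73 and 30.7 FPKM after it, Tagln rose by 1.5 (SE 0.40), and Rgs5 fell by 1.12 and lost its call with TMM scaling (-0.56, adjusted p = 0.0511). Of 14 endothelial markers 1 rose, Egfl7, and 2 fell, Emcn and Kdr (1 and 2 adjusted over the list alone; camera adjusted p = 0.00632, adjusted p = 0.757 with an estimated correlation). Camera placed the endothelial list above the other genes. All tested genes had a median of -0.63, so the call of this list is no rise in itself. With TMM scaling Kdr lost its call (adjusted p = 0.2). Of 13 TGF-beta and BMP genes 3 rose, Smad6, Id1 and Id3, and 1 fell, Bambi (3 and 1 adjusted over the list alone; camera adjusted p = 7.31e-05, adjusted p = 0.621 with an estimated correlation). Smad6, Id1 and Id3 are direct targets of BMP signalling. Bambi lost its call with TMM scaling (-0.54, adjusted p = 0.0654). Cyr61, a matricellular protein gene and Hippo target, rose by 1.78 (SE 0.32, adjusted p = 0.00245).

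Of 20 oxidative phosphorylation genes 17 fell (18 adjusted over the list alone; median -1.52; camera adjusted p = 0.000137, adjusted p = 0.757 with an estimated correlation). With TMM scaling 14 fell. Uqcrc2 fell from 31.3 ± 7.03 to 4.37 ± 0.924 FPKM and Ndufb9, a complex I subunit, from 48.1 ± 11.7 to 12.8 ± 2.79. Of 20 unfolded protein response genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; median -1.46; camera adjusted p = 0.0184, adjusted p = 0.757 with an estimated correlation). With TMM scaling 12 fell and 2 rose. Sdf2l1 fell by 3.15 (SE 0.24, adjusted p = 9.53e-05), Manf by 2.01, Pdia4 by 1.74 and Hsp90b1 by 1.40. Of 17 cholesterol synthesis genes 14 fell (14 adjusted over the list alone; median -1.18; camera adjusted p = 0.0106, adjusted p = 0.757 with an estimated correlation), and 7 with TMM scaling. Fdps (farnesyl diphosphate synthase) fell by 2.74 (SE 0.43) and Lss (lanosterol synthase) by 1.41 (SE 0.23), while Srebf2, the transcription factor of the pathway, fell by 0.89 and lost its call with TMM scaling (adjusted p = 0.107).

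Beta cell identity genes were not called as a list (camera adjusted p = 0.0867), but 16 of 27 fell and 2 rose (19 and 2 adjusted over the list alone), and with TMM scaling 10 fell and 3 rose. Pcsk1 fell by 2.53 (SE 0.35), Slc2a2 by 2.56 (SE 0.42), Glp1r by 1.51 and Prlr, the prolactin receptor, by 1.56, while Gipr, the receptor of the incretin GIP, rose by 1.21 (SE 0.31, adjusted p = 0.011). Of 9 alpha cell markers 5 fell, including Gcg (log2 difference -2.60), Ttr and Slc7a2, and of 7 delta and PP cell markers 4 fell: Sst (-1.94), Rbp4 (-2.30), Pyy (-1.49) and Ppy (-1.34, SE 0.49, adjusted p = 0.0464). Ppy lost its call with TMM scaling (adjusted p = 0.194), as did Pyy (adjusted p = 0.0773). Ins2 was at -2.70 (SE 1.11, adjusted p = 0.0729) and Mki67 at 0.85 (SE 0.34, adjusted p = 0.0681). The beta cell disallowed and immaturity genes passed as a list that stood above the other genes (camera adjusted p = 0.0262, adjusted p = 0.757 with an estimated correlation), although its mean was -0.17, its median 0.22, and its 2 called members, Neurog3 and Oat, fell (2 adjusted over the list alone). Class II genes fell again (Cd74 by 2.49, H2-Aa by 1.77), Cd14, a lipopolysaccharide co-receptor of macrophages, rose by 2.05 (SE 0.53), or by 2.99 without KO after-PPx library 7 and 1.12 without library 8. Without library 8 neither Cd14 nor Col1a1, Fn1 or Tagln was called. Of 16 insulin and IGF signalling genes 8 fell, among them Akt2, Akt3, Pik3r1 and Foxo1 (8 adjusted over the list alone). With TMM scaling Akt2, Pik3r1 and Foxo1 were not called (adjusted p = 0.054, 0.189 and 0.21). Of 24 SWI/SNF subunits 5 fell and 1 rose, Pbrm1 falling by 1.29 and Brd9 rising by 0.72. The alpha cell, delta and PP cell, insulin and IGF, and SWI/SNF lists were not called by camera. Of all 13295 tested genes 5144 were called lower in this comparison, so falls within these lists do not set them apart.

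The 8 rises that the rule names in KO after PPx were Col1a1, Mir6984, Rnu11, Mir6927, Snora68, Hspa1b, Mir328 and Erdr1. The 8 falls were Amy2a5, Usmg5, Cox6c, Amy2b, Ndufa1, Ndufa4, Ndufc1 and Rpl37a. The first 7 of these were listed at 0 in both after-PPx libraries, so their place in the rule depends on the pseudocount and is no rank by size. Amy2a5, a pancreatic amylase gene, had 110, 573, 819, 56.4 and 1969 FPKM in the KO libraries without PPx, and acinar markers as a list were not called (median -2.59; camera adjusted p = 0.581), with 2 of 27 falling and 0 adjusted over the list alone. The count was 3379 without KO after-PPx library 7, and 2389 genes were called in every fit that left out 1 library. TMM scaling moved the median of all genes from -0.63 to -0.20 and the split to 1451 higher and 2822 lower, median-of-ratios scaling (median -0.14) to 1701 and 2497. Of the 5588 genes, 2285 were called under both and with a trend on transcript length removed as well.

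The interaction of genotype and PPx, which tests whether the PPx effect differed between KO and control, was negative for nearly all genes called, among them Sdf2l1, Uqcrc2 and Cd74. Sdf2l1 was at 31.5 FPKM on average without PPx and 27.6 after it in controls, and at 40.8 and 3.76 in KO (log2 difference of the effects -2.98, SE 0.38, adjusted p = 0.0116). Cd74 was at 61.9 and 71.4 in controls and 70.4 and 12.9 in KO (-2.72, adjusted p = 0.0239), and Glp1r at 194 and 209 in controls and 291 and 101 in KO (-1.60, SE 0.30, adjusted p = 0.0357). Sdf2l1, Uqcrc2 and Cd74 kept their calls with TMM scaling, but Glp1r did not (-1.04, adjusted p = 0.0975; median-of-ratios scaling -0.96, adjusted p = 0.125). Of the 11 fits that left out 1 library, Sdf2l1 was called in 10, Cd74 in 4, and Uqcrc2 and Glp1r in 3 each. Limma called 267 genes, 5 positive and 262 negative. Since KO after PPx is the group with the high Rn45s share and low depth, this term takes up any difference of those libraries. Nr4a1 (0.43, SE 0.48), Nr4a2 (0.81, SE 0.69) and Nr4a3 (1.45, SE 0.49) were not called (adjusted p = 0.593, 0.479 and 0.114), nor were Ins1 (-2.46, SE 0.88, adjusted p = 0.13), Ins2 (adjusted p = 0.367), Gcg (adjusted p = 0.108), Sst (adjusted p = 0.083), Ppy (adjusted p = 0.471), Mki67 (adjusted p = 0.494) or Arid1a (adjusted p = 0.891).

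By camera 9 lists passed with a preset correlation, and with an estimated one adjusted p = 0.923 for each of them. Of 20 oxidative phosphorylation genes 3 had a negative interaction (11 adjusted over the list alone, median -1.26, camera adjusted p = 0.0022). They were Uqcrc2 (-2.46, SE 0.47), and Cox6c and Ndufa4, which were listed at 0 in both KO libraries after PPx. A negative interaction was also called in 1 of 20 unfolded protein response genes (6 adjusted over the list alone, adjusted p = 0.0241). It was called in 2 of 13 macrophage and dendritic cell markers, Cd74 and H2-Aa (3 adjusted over the list alone, list not called). H2-Aa lost its call with TMM scaling (adjusted p = 0.0844). Beta cell identity genes had 1, Glp1r (8 adjusted over the list alone; adjusted p = 0.0657), and cholesterol synthesis 1, Srebf2, which lost its call with TMM scaling (-0.46, adjusted p = 0.326). The Nr4a, TGF-beta and BMP, ERK, stromal, acinar, immediate early and Reg lists stood above the other genes (adjusted p = 0.0022, 0.0022, 0.00931, 0.00927, 0.00931, 0.00931 and 0.0473), with 0 members called. The signs differed within these lists: the median was -0.59 and the mean -0.69 for acinar genes, -0.08 and -0.07 for immediate early genes, -0.13 and 0.00 for stromal genes and 0.03 and -0.03 for ERK genes. The positive interactions were Mir6984, Mir6927, Snora68, Mir6898 and Stmn1-rs1, and the negative ones that the rule names were Usmg5, Cox6c, Mrpl42, Ndufa4, Ndufc1, Snrpg, Atp5e and Mir344c, all listed at 0 in both KO libraries after PPx. TMM scaling gave 98 genes, 5 positive and 93 negative. Only 8 of the 267 were called in every fit that left out 1 library, and the count ran from 11 without control after-PPx library 5 to 3463 without KO after-PPx library 8. It was 66 without control after-PPx library 6, 21 and 1001 without control no-PPx libraries 9 and 11, and 897, 61, 58, 53 and 50 without KO no-PPx libraries 12 to 16.

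With PPx as a term in the model, KO islets had higher fitted values of immediate early genes and Nr4a receptors than controls, with 0 called over all genes. By exact permutation of list means, which leaves PPx out, the lists differed by 0.35 (p = 0.348) and 0.88 (p = 0.185). Adjusted over the lists tested, permutation p = 0.976 for both, so no genotype effect is shown at the level of libraries. All 16 immediate early genes were positive (median 0.66; 0 called over all genes and 7 adjusted over the list alone; camera adjusted p = 2.03e-18, adjusted p = 0.0525 with an estimated correlation), Fosb by 0.93 (SE 0.21), Klf4 by 0.88 (SE 0.22), Junb by 1.01 (SE 0.30) and Btg2 by 0.71 (SE 0.22). The Nr4a receptors had a median of 1.34 (2 adjusted over the list alone; camera adjusted p = 1.01e-08, adjusted p = 0.0525 with an estimated correlation), with 1.34 (SE 0.24) for Nr4a1 and 1.78 (SE 0.35) for Nr4a2. The 18 ERK genes (13 positive and 5 negative, median 0.25, with Etv5 and Etv1 at -0.30 and -0.29, camera adjusted p = 1.28e-05, adjusted p = 0.276 with an estimated correlation), with Errfi1 at 1.01 (SE 0.27), and 13 of 13 TGF-beta and BMP genes (camera adjusted p = 3.19e-07, adjusted p = 0.276 with an estimated correlation) were also higher as lists.

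No single gene passed: limma called 0, the smallest adjusted p was 0.836, and 643 genes had an unadjusted p below 0.05 against 665 expected by chance. It called 0 with array weights and under each scaling, 1 without KO after-PPx library 7 and 1 without the library labelled KO no-PPx 14. Acinar, stromal and Hippo lists passed as well (camera adjusted p = 7.33e-05, 0.0234 and 0.0414; each adjusted p = 0.978 with an estimated correlation). Hormone genes had Ins1 at -1.05 (SE 0.61), Ins2 at -0.87 (SE 1.06), Gcg at -1.10 (SE 0.60), Sst at -0.18 (SE 0.38) and Ppy at -1.10 (SE 0.40), and Mki67 -0.11 (SE 0.27). Besides Nr4a1, Nr4a2 and Fosb, the smallest p on the higher side were those of Klf2 (0.74, SE 0.17) and the predicted gene Gm19461, and on the lower side of Smim24, Tfap4, Mir6353, Tmem191c and Ndor1 (-0.92, SE 0.22).

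With genotype as a term, islets after PPx had higher values than islets without PPx of the Hsp70 genes Hspa1a and Hspa1b and their co-chaperone Dnajb1, of the Nr4a receptors and of some immediate early and stromal genes. A mean over 18 other heat shock genes differed by 0.02 (exact permutation p = 0.891, 1 rose and 1 fell), a list chosen after the values of Dnajb1 and Hspa1a had been seen. This pooled value covers a higher level after PPx in controls only. Controls had 4.17 and 4.6 without PPx and 4.79 and 4.66 after it. KO libraries had 4.35 to 4.98 without PPx and 4.15 and 4.71 after it. Dnajb1 rose by 2.36 (SE 0.20, adjusted p = 0.00119), with 12.3 to 24.5 FPKM in the 7 libraries without PPx and 53.4 to 109 in the 4 after it, and Hspa1a and Hspa1b rose by 3.41 (SE 0.51) and 3.50 (SE 0.54). Nr4a1 rose by 2.12 (SE 0.24, adjusted p = 0.00702). Pdyn, the precursor of dynorphin opioid peptides, fell by 2.46 (SE 0.35, adjusted p = 0.0141). Dpp4 (log2 difference -1.53, SE 0.19, adjusted p = 0.00946) and Greb1l (-1.78, SE 0.25, adjusted p = 0.0141) lie outside the rule for named genes here, were chosen after their values were seen, and fell in every fit that left out 1 library, as Dnajb1 and Nr4a1 rose in every one.

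Of 16 immediate early genes 8 rose (9 adjusted over the list alone; median 0.76; camera adjusted p = 2.43e-14, adjusted p = 0.103 with an estimated correlation), and 15 with TMM scaling. Jun rose by 0.77 and Zfp36 by 1.15, and Hspa1a and Hspa1b also belong to this list. The TMM count adds no support, since that scaling raises all genes of the KO libraries after PPx. All 3 Nr4a receptors rose (3 adjusted over the list alone; camera adjusted p = 1.64e-06, adjusted p = 0.103 with an estimated correlation). Of 18 stromal markers 5 rose (10 adjusted over the list alone; median 1.13; camera adjusted p = 2.28e-11, adjusted p = 0.42 with an estimated correlation), Col1a1 by 4.01 (SE 0.82), Col3a1 by 2.99 (SE 0.79), Fn1 by 2.44 (SE 0.62, and 1.39 without KO after-PPx library 8) and Tagln by 1.29 (SE 0.31). Of 18 ERK genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.000326, adjusted p = 0.42 with an estimated correlation), Phlda1 rising by 1.36 and Etv1 falling by 1.03. Of 13 TGF-beta and BMP genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.000167, adjusted p = 0.551 with an estimated correlation), and of 14 endothelial markers 1 rose, Egfl7 (1 adjusted over the list alone; camera adjusted p = 0.000128, adjusted p = 0.69 with an estimated correlation). Cyr61 rose by 1.65 (SE 0.25) as 1 of 9 Hippo targets (1 adjusted over the list alone; camera adjusted p = 0.00592, adjusted p = 0.69 with an estimated correlation).

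Lists that stood lower after PPx were those of respiration, protein folding, cholesterol synthesis and acinar cells. Of 20 oxidative phosphorylation genes 9 fell (17 adjusted over the list alone; median -1.03; camera adjusted p = 0.000555), of 20 unfolded protein response genes 11 (13 fell and 2 rose adjusted over the list alone; median -0.94; camera adjusted p = 0.0251), of 17 cholesterol synthesis genes 7 (10 adjusted over the list alone; median -0.86; camera adjusted p = 0.00592) and of 27 acinar markers 4 (15 adjusted over the list alone; median -2.53; camera adjusted p = 0.00606). With an estimated correlation adjusted p = 0.716 for each of the 4 lists. Pdia6, a protein disulfide isomerase, fell by 1.16 (SE 0.28), Sel1l by 0.88, Sdf2l1 by 1.92, Fdps by 1.98 and Cpa2, a pancreatic carboxypeptidase, by 3.04 (SE 0.93). These values average over genotypes that differed. In controls alone the differences were -0.46, -0.45, -0.16, -0.89 and -2.68 in this order, none called. In KO they were -1.65, -1.18, -3.15, -2.74 and -3.30, from the after-PPx libraries that stood apart. SWI/SNF, interferon and beta cell immaturity lists stood above the other genes (camera adjusted p = 0.00617, 0.00425 and 0.0164; adjusted p = 0.69, 0.69 and 0.716 with an estimated correlation), with 0 rising and 2, 0 and 1 falling (0, 0 and 1 adjusted over the list alone). The mean of the SWI/SNF list was -0.03 and its median 0.03. Beta cell identity genes were not called as a list (camera adjusted p = 0.197), with 9 of 27 falling and 2 rising (11 and 2 adjusted over the list alone): Ffar1, a fatty acid receptor, fell by 1.17, Prlr by 1.02, and Gipr rose by 0.97. Sst fell by 1.21 (SE 0.38, adjusted p = 0.047) and lost its call with TMM scaling (adjusted p = 0.0687), as did Cpa2 (adjusted p = 0.055), whereas Ins1 (-1.33, SE 0.61), Ins2 (-1.64, SE 1.06), Gcg (-1.51, SE 0.60), Ppy (-0.97, SE 0.40) and Mki67 (0.60, SE 0.27) did not pass. In controls alone Ffar1, Prlr, Gipr and Sst were at -0.50, -0.24, 0.61 and -0.15, none called, and in KO at -1.64, -1.56, 1.21 and -1.94. Other rises that the rule names were in Mir7028, Mir7045, Mir7052 and Mir6942, and other falls in Mir186, Snord98, Ggh, Ndufb6, Mcee, Tvp23b and Tmsb15b1.

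Limma called 2654 genes with genotype as a term, 336 higher and 2318 lower, and TMM scaling, which moved the median of all genes from -0.38 to -0.13, gave 905 and 1464. Without both KO libraries after PPx, a setting added after the data were seen, it called 0, with 986 genes at an unadjusted p below 0.05. The medians were then 0.78 for immediate early genes, 1.17 for stromal markers, -2.32 for acinar markers, -0.20 for oxidative phosphorylation, -0.22 for the unfolded protein response and -0.21 for cholesterol synthesis. The log2 difference was 2.28 for Dnajb1 and 1.87 for Nr4a1. With array weights limma called 0, and with the acinar marker mean as a covariate 2. The count was 24 without KO after-PPx library 7, 17 without 8, 1619 without control after-PPx library 6, 4117 without 5, 644 without control no-PPx library 11, 5037 without 9, and 24, 27, 26 and 30 without KO no-PPx libraries 13, 14, 15 and 16, with 10 genes called in every such fit. In an exact two-sided permutation test of list means over the 330 splits of 4 against 7 libraries, the immediate early list differed by 0.88 (p = 0.00303), the Nr4a list by 1.42 and oxidative phosphorylation and cholesterol synthesis by -1.18 and -0.82 (each p = 0.00909), and stromal markers by 1.23 (p = 0.0152). Adjusted over 26 lists these were 0.0591, and 0.0659 for stromal markers. Hspa1a and Hspa1b, whose reads cannot be told apart, count as separate members in the immediate early mean. The adjusted value for the genotype was 0.976 for each list.

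**Figure D4:**
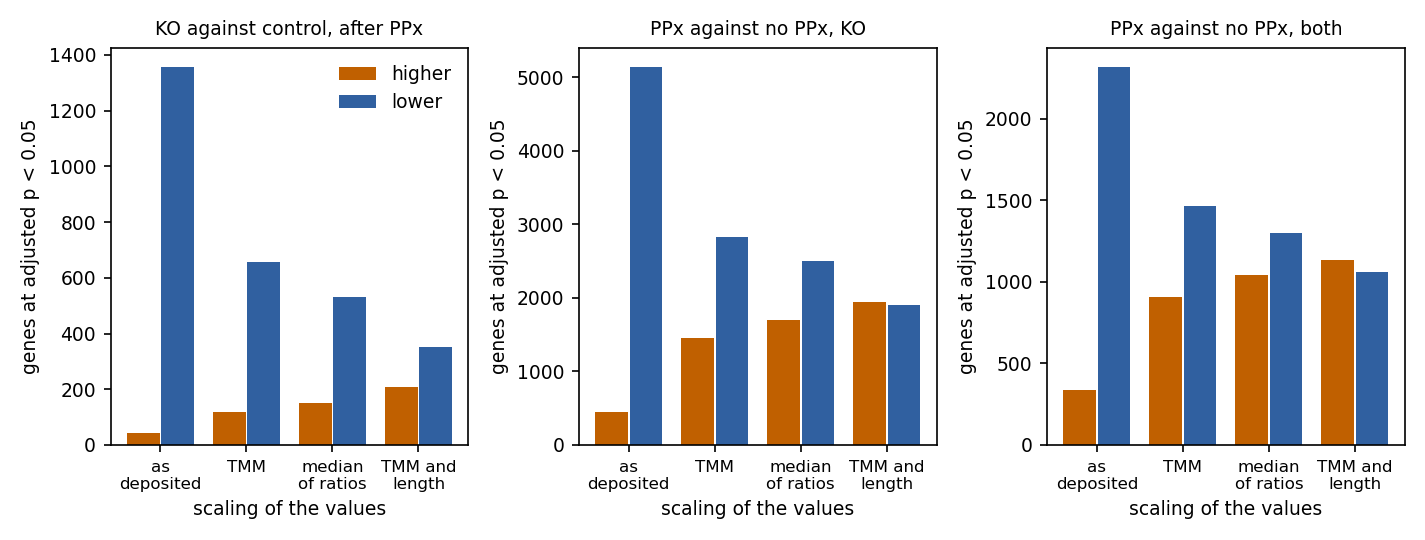
Number of genes called higher and lower at an adjusted p below 0.05 as deposited and after 3 rescalings, for KO against control after PPx, PPx against no PPx in KO, and PPx against no PPx with genotype as a term. In each comparison fewer genes are called lower and more higher after rescaling, for example 444 higher and 5144 lower as deposited and 1451 and 2822 with TMM scaling for PPx in KO.

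Across the 13295 genes, the genotype effect without PPx and that after PPx were nearly unrelated (Pearson r = -0.031, Spearman rho = -0.064). The sign was the same in 35.8% of genes, with medians of 0.12 and -0.47. Without PPx 0 genes were called, and the effect after PPx rests on the KO libraries that stood apart. The low correlation thus does not show that loss of Arid1a acts differently in the states. The effects of PPx in control and KO islets had r = 0.40 and rho = 0.43. These values are across genes, which are not independent replicates, and no library enters both effects of a pair. The genotype value was -0.15 without control no-PPx library 11, 0.17 without library 9 and -0.12 without KO no-PPx library 12, and the PPx value 0.10 and 0.52 without control no-PPx libraries 11 and 9 and 0.29 without control after-PPx library 6.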

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

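The test of a differing PPx response by the depth of the KO libraries, the use of median-of-ratios scaling in the test of scaling by total, and the removal of the trend on transcript length were chosen only after the results had been seen. In 267 genes the effect of PPx differed between KO and control by the interaction term of limma. Among the genes named, those with a more negative effect in KO had interaction log2 differences of -2.98 for Sdf2l1, -2.46 for Uqcrc2, -2.72 for Cd74, -2.04 for H2-Aa, -1.60 for Glp1r, -0.97 for Fam46a, -1.92 for Pdyn and -1 for Srebf2. With TMM scaling Sdf2l1, Uqcrc2 and Cd74 kept their calls, and H2-Aa (adjusted p = 0.0844), Glp1r (0.0975), Fam46a (-0.43, adjusted p = 0.322), Pdyn (0.206) and Srebf2 (-0.46, adjusted p = 0.326) lost theirs. Of 11 fits that left out 1 library, Sdf2l1 was called in 10, Cd74 in 4 and Uqcrc2 in 3. For genes listed at 0 in both KO libraries after PPx the fitted values depend on the pseudocount and are no measure of size: -5.16 for Cox6c, -5.56 for Usmg5, -4.45 for Ndufc1, -4.09 for Mir344c, -4.12 for Atp5e, -3.44 for Toporsos, -3.96 for Polr2f, -3.93 for Ndufa1, -4.24 for Snrpg, -4.90 for Mrpl42, -4.57 for Ndufa4 and -2.71 for Mir490. The same holds for Mir6927 (3.95), listed at 0 in the 5 KO libraries without PPx. Also more positive in KO were Stmn1-rs1 (2.48), Snora68 (3.45), Mir6984 (4.64) and Mir6898 (3.01), a pseudogene and small RNAs.

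Behind the negative terms stand the 5144 genes called lower after PPx in KO, whose 2 after-PPx libraries have low depth and a high Rn45s share. Low depth that turns values to 0 stays open. Of the genes, 32.4% lay below the median of tested genes by mean value. This share cannot decide, since a gene with a low value can fall only little on the log2(FPKM + 1) scale and is less likely to be called whatever the cause. Libraries 7 and 8 also listed 199 and 54 genes at 0 that had a median above 10 FPKM over the other libraries. Scaling by total, with ribosomal RNA taking part of it, stays open, since the share of these genes still called lower was 54.9% with TMM scaling and 48.5% with median-of-ratios scaling, on both sides of the bound of 50% set for its exclusion, and their median went from -1.25 to -0.80 and -0.73 while that of all genes went from -0.63 to -0.20 and -0.14. Loss of short transcripts stays open as well: the median effect ran from -0.75 in the fifth of genes with the shortest transcripts to -0.49 in that with the longest in KO (-0.05 to -0.01 in controls), but the share of genes called lower was 30.7% among those shortest genes and 38.6% to 42.1% among longer ones; with TMM scaling and the length trend removed 38.4% of 4962 genes with a known length were still called, with a median of -0.61 against 0 for all genes. A response to PPx that differs without Arid1a may also account for part of the pattern and cannot be told apart from RNA quality, because 0 of the 2 KO libraries after PPx had a depth inside the range of the other libraries.

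Some libraries of the KO group without PPx lay far from the other 4, by a gap to the nearest library of more than 0.71 of the whole range of the 5. Of 179 measures 21 did so, where 8.9 are expected by chance for unselected measures with normal values. The measures were not of that kind. Some overlap, such as the Nr4a list and Nr4a1, and some genes were named for values listed at 0 in most of these libraries. The excess over 8.9 therefore decides nothing. In KO no-PPx library 13 these were low means of the Nr4a receptors (0.735) and of the immediate early genes (0.773) and low Nr4a1 (0.775). Library 12 had low Gcg (0.757), Sel1l (0.736), Cd14 (0.747), Slc7a2 (0.853), Tvp23b (0.766) and Pbrm1 (0.771) and high Mir6945 (0.916) and Mir6898 (0.739). Library 15 stood apart in Erdr1 (0.754) and Mir490 (0.798), the library labelled KO no-PPx 14 in Mir7052 (0.94), and library 16 in the endothelial list (0.91). A ratio of 1 marks genes listed at 0 in the other 4 libraries: Pnp2 in library 13, Smim24 and Mir6984 in library 15, Polr2k and Mir7006 in the library labelled KO no-PPx 14, and Fn1 in library 16.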

How the results depend on the processing

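Leaving out control library 9 and KO library 12 without PPx (the shallower libraries), leaving out both KO libraries after PPx, removing the trend on transcript length and keeping protein-coding genes only were chosen after seeing the data. No paired analysis was possible because the replicate numbers of the groups do not overlap. Count tests on whole reads with edgeR and DESeq2 were planned and not run, because whole reads cannot be recovered from FPKM. Where a fit left a group with 1 library, that library was assumed to vary like the other groups. The cause of each change of a count below was not tested, except that fits with fewer libraries have fewer degrees of freedom. The filter on low values left 6747 genes untested, and read counts behind a value are unknown. KO after-PPx libraries 7 and 8 listed 199 and 54 genes at 0 that had a median above 10 FPKM over the other libraries. Losses in them were thus not confined to low values.

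For KO against control after PPx (1400 genes) the count was 774 with TMM scaling, 681 with median-of-ratios scaling, 558 with TMM scaling and the length trend removed (208 higher, 350 lower), 40 with array weights, 0 with only the 2 groups compared and 2329 with the acinar marker mean as covariate. For PPx in KO (5588) it was 2365 with array weights and 2778 with the acinar covariate; TMM scaling with the length trend removed gave 1950 higher and 1903 lower. For the interaction (267) it was 410 with pseudocount 0.25, 32 with pseudocount 4, 127 with no filter on low values, 512 with a mean of at least 5, 98 with TMM scaling, 84 with median-of-ratios scaling, 109 without the trend, 7 with array weights, 849 with the acinar covariate, 75 without the shallower libraries and 52 with the length trend removed. For PPx with genotype as a term (2654) it was 0 with array weights, 2 with the acinar covariate, 0 without both KO libraries after PPx and 5163 without the shallower libraries; median-of-ratios scaling gave 1041 higher and 1299 lower, and the length trend removed 1136 and 1058. Without the shallower libraries, KO against control without PPx and PPx in control each had 1 gene in place of 0.

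Leaving out 1 library at a time, the counts of genes ran from 0 to 2 for KO against control without PPx, 53 (without control_PPx 5) to 4038 (without KO_PPx 8) after PPx, 0 to 5 for PPx in control, 3379 to 6421 for PPx in KO, 11 to 3463 for the interaction, 0 to 1 for genotype with PPx as a term and 17 to 5037 for PPx with genotype as a term. The counts of lists ran from 2 to 5 (4 without control_noPPx 9, 5 without KO_noPPx 12), 6 (without control_PPx 5) to 11, 7 to 13, 8 to 15, 1 (without control_noPPx 11; 3 without control_PPx 5 and 5 without KO_PPx 8) to 11, 5 to 10, and 12 to 18 in the same order.

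With an estimated correlation 0 lists passed in each of the 7 comparisons, in place of 2, 10, 9, 10, 9, 7 and 14. With fry, which tests whether the genes of a list move one way, 0, 2, 0, 10, 0, 1 and 2 passed. The correlation of genotype effects was 0.056 with the acinar covariate and 0.091 without the shallower libraries and ran from -0.15 to 0.17 leaving out 1 library; that of PPx effects was 0.54 without the shallower libraries and ran from 0.10 to 0.52.

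Of 222 calls of named genes, 37 held in every alternative. Snap25, a gene of neuroendocrine exocytosis called lower after PPx in KO (log2 difference -0.65), reversed to 0.02 with median-of-ratios scaling and to 0.25 with TMM scaling and the length trend removed, neither of them called. Of 6322 values of genes that were not called, 162 had the other sign.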

Other observations

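The tests of handling stress, of a response to PPx itself and of PPx as a source of the acinar difference were chosen only after the results had been seen. Acinar genes, which encode digestive enzymes and are not expressed by islet cells at high levels, varied by library. The mean log2 value of 27 markers was 2.59 and 7.80 in the controls without PPx, 3.39, 6.46, 6.62, 5.66 and 8.14 in the KO libraries without PPx, and 2.77 to 3.27 in the 4 libraries after PPx. Cela3b, an elastase gene, ranged from 15.8 to 891 FPKM and Clps, pancreatic colipase, from 17.4 to 462.

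The acinar genes moved together within groups, with a median correlation of 0.92 between pairs of the 27 markers after group means were removed. Acinar tissue carried along with the islets is therefore a candidate source of this variation. PPx as the source of the lower values stays open, since 1 library without PPx (control library 9, at 2.59) lay below the lowest library after PPx; the bound this test needed was raised after that value was known.

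The mean of 16 immediate early genes was 5.86 to 6.77 in the libraries after PPx and 4.69 to 5.62 in those without. Of the 16 genes 0 were called in control, 6 in KO and 8 with genotype as a term, and the list did not pass with an estimated correlation (adjusted p = 0.313, 0.271 and 0.103). The explanation that only the 2 KO libraries after PPx carry it is argued against by a value of 104% without them (1.04). That value rests on 2 against 2 control libraries, with 0 members called. The 16 members include Hspa1a and Hspa1b, at 3.71 and 3.77 in controls. Their reads cannot be told apart, so the mean difference leans on a signal that is counted more than once. Leaving out 1 library moved the PPx difference in controls between -0.43 and 1.18 for Junb and between -0.51 and 0.59 for Btg2. It stayed at 0.5 to 1.05 for Fosb and 0.68 to 0.97 for Klf4. The test of scaling by total decides nothing, since TMM scaling, with its low factors in the KO libraries after PPx (0.632 and 0.869), raises all their genes, and it gave 135% of the difference as deposited (1.35 against 1.00). A response to PPx itself and a general stress of tissue handling both stay open. Of the 7 libraries without PPx, 0 lay above the lowest after PPx, which either would give. The mean of 18 other heat shock genes differed by 0.02 (exact two-sided permutation p = 0.891 over 330 splits, 1 rose and 1 fell). In controls this mean was 4.17 and 4.6 without PPx and 4.79 and 4.66 after it. In KO after PPx it was 4.15 and 4.71, so the pooled value decides nothing. Dnajb1, Hspa1a and Hspa1b, not among the 18, rose by 2.36, 3.41 and 3.50.

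Other splits of the 11 libraries were drawn for the 2 comparisons over both states. For PPx with genotype as a term, 1 of 99 splits, the real one, called as many genes, 2654 against at most 2 in the others. The real split holds both KO libraries after PPx, which stood apart from the rest, in the same arm. The split test cannot tell PPx from the state of those libraries, so no conclusion is drawn from it for the number of genes. For gene lists 5 of 99 splits called as many, 14 in the real one and at most 15 in the others, so chance is not excluded. For genotype with PPx as a term, all 100 splits called at least the 0 genes of the real one, at most 3, and 32 of 100 called at least its 7 lists, at most 13, so chance is not excluded for either.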
